A study of Mus musculus with 31 samples.

How the data were processed

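The values are log2 intensities per probe set that the authors obtained with RMA (robust multi-array averaging: background correction, quantile normalization and a summary over the probes of a set), per the labels' processing field; the RMA version and its settings are not stated. Per the labels' protocols, total RNA of lung tissue was turned into biotin-labelled cRNA and handled by the standard Affymetrix protocol. Each array is 1 column of deposited log2 values for 35556 probe sets, with 1 column for each of the 31 arrays. The distributions fall into 2 sets of arrays, 18 with medians from 6.96 to 7.10 and maxima up to 14.0, and 13 with medians from 6.80 to 6.90 and maxima from 14.1. The sets may have been normalized separately, which no label states. The larger set holds all C57 arrays and the AKR arrays titled 6 weeks of room air; the smaller one holds all other AKR arrays.

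Probe sets were named through the platform annotation supplied with the values, which lists 23410 of them. Of these, 21789 carry 1 gene symbol and 1621 carry several; the other 12146 probe sets are unnamed here, and no gene was named from a probe set with several symbols. Symbols were updated through Entrez identifiers, of which 99.6% matched the RefSeq gene table. A gene with several probe sets (999 genes) was represented by the one with the highest mean over all arrays, which gave 19938 genes. Of these, 14705 lay above the 40th percentile of an array's probe sets on at least 3 arrays and were tested.

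Differences were tested with limma: 1 fit of 11 group means to all 31 arrays (20 residual degrees of freedom), contrasts between groups, empirical Bayes moderation, and Benjamini-Hochberg adjustment over the genes of each contrast. The test is two-sided, and a gene passed at an adjusted p under 0.05. "Rose" and "fell" are used for genes that passed. Errors given after ± are standard errors of the log2 fold change from this fit, unless SD is written. Interactions are differences of differences in the same fit. In simulated data with 200 changed genes among 14705, the fit recovered 88% of changes of 1 log2 unit and 98% of changes of 2 units for LPS against saline after air in C57, and 75% and 97% for the strain by LPS interaction. The corresponding shares were 90% and 99% for smoke against air with saline in AKR, and 84% and 98% for smoke against air with LPS in AKR. The simulated noise was normal, with each gene's own spread, and independent between genes and arrays. It held no difference shared by many genes of an array, so these shares do not give the recovery to be had in the real data.

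Before the data were examined, the comparisons, the alternatives and 33 gene lists were fixed. The lists cover inflammatory cytokines and chemokines, interferon-stimulated genes, interferon gamma-induced genes, acute-phase proteins, NF-kB feedback genes, targets of the aryl hydrocarbon receptor and of NRF2, major histocompatibility complex genes, endothelial activation, extracellular matrix, cell cycle, the unfolded protein response, p53 targets, immediate early genes and circadian clock genes. They also cover markers of neutrophils, macrophages, monocytes, T cells, regulatory T cells, natural killer cells, B cells, dendritic cells, thymocytes, endothelium, alveolar type 1 and type 2 cells, club cells, ciliated cells, heart muscle, adipocytes and erythroid cells, and a list of genes at loci known to differ between the strains. The major histocompatibility list also holds B2m and Cd74, whose genes lie outside the complex. The 29 lists with at least 5 tested members, other than the strain loci, were tested with limma's camera at a preset correlation between genes of 0.01, with Benjamini-Hochberg adjustment over the lists of a contrast. Camera with a correlation estimated from the data, and fry, were run beside it.

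The genes named are, for each comparison, the 8 with the largest positive and the 8 with the largest negative log2 fold change among those that passed, and up to 4 members of each list with the largest absolute change, passing or not. Added to these are fixed genes of the LPS and smoke responses and, between strains, the strain loci. Genes named outside that rule are said to have been chosen after their values were seen. Counts without both arrays whose values depart from their labels, the strain comparison by differences within a set of arrays, and the strain by LPS interaction against room air alone were added after the data were seen.

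The work was done with R 4.3.3, limma 3.58.1, statmod 1.5.0 and data.table (1.17.8), and figures were drawn with Python 3.11.15 and matplotlib 3.10.9.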

Results

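The data are 31 gene expression arrays of whole lung from male mice of 2 inbred strains, AKR and C57BL/6 (C57 from here on). The mice breathed cigarette smoke or room air, and most of them then received lipopolysaccharide (LPS, the endotoxin of Gram-negative bacteria) in saline, or saline alone, through the trachea. These treatments form 8 groups of 3 arrays, except for AKR smoke LPS, which has 2. A further 3 groups had room air alone: 3 C57 arrays and 3 AKR arrays titled 6 weeks, and 2 AKR arrays titled 3 weeks. The sample titles give the instilled mice 3 weeks of exposure, whereas the series description gives 6 weeks to instilled mice and 3 weeks to the others, so the exposure time of each group is uncertain. None of the 31 arrays is of a smoke-exposed mouse without instillation. The number of arrays per group limits the precision of every value.

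Arrays of the same group correlated at 0.961 to 0.993 over the genes tested. Principal component 1 (43.0% of the variance) separated LPS from the other treatments, and component 2 (28.0%) separated the sets of arrays, being positive on all 18 of the larger set, AKR room air at 6 weeks included, and negative on all 13 of the smaller one. A pair of C57 arrays stood on the wrong side of component 1 for their labels. The array labelled C57 smoke saline 3 had log2 intensities of 12.5 for Saa3 (serum amyloid A3, an acute-phase protein) and 11.1 for Cxcl2 (a neutrophil chemokine), and the array labelled C57 smoke LPS 3 had 6.1 and 5.2. On the other smoke saline arrays of C57 Saa3 read 6.1 and 6.4, and on the other smoke LPS arrays 12.6 and 12.8. All arrays were kept under their labels, and the counts without this pair are given beside the main ones. Both arrays enter the shared estimate of the spread, so they widen the errors of LPS-response genes in every comparison. For such genes the errors after ± do not measure the spread within the groups compared. For LPS after air in C57 the smallest limma adjusted p was 4.6e-04 with the pair and 3.6e-13 without it.

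**Figure D1:**
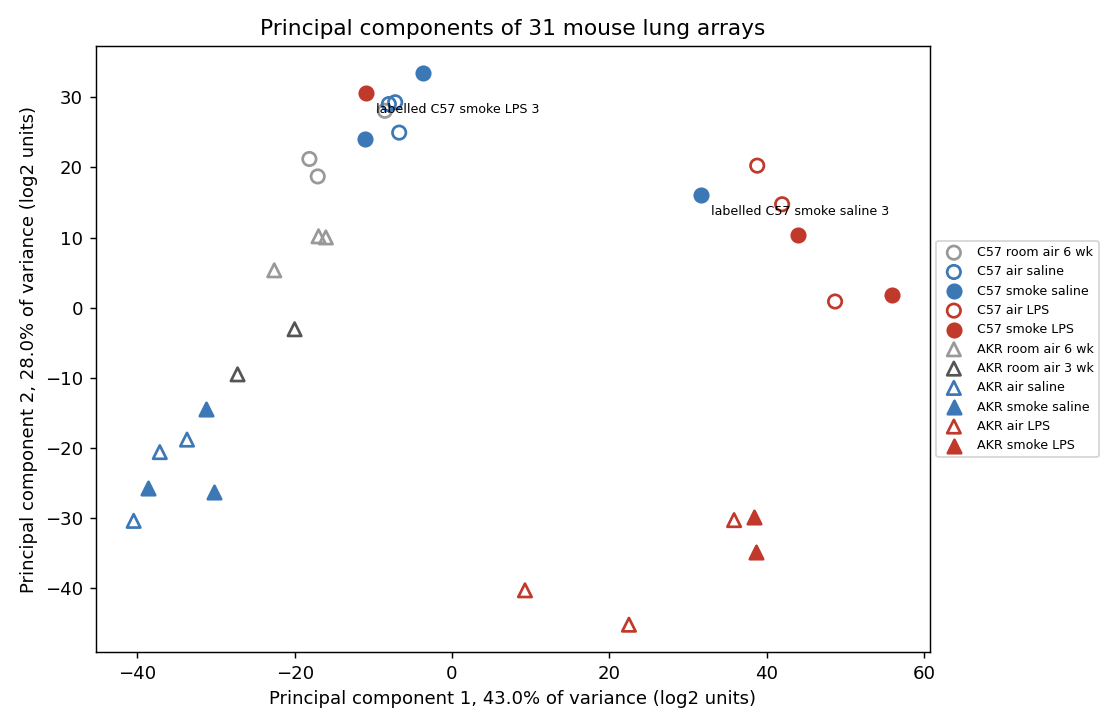
Position of the 31 arrays on the first 2 principal components of the tested genes, which hold 43.0% and 28.0% of the variance. Circles are C57 and triangles AKR, filled symbols smoke and open symbols air, red LPS, blue saline, grey room air alone; the arrays labelled C57 smoke saline 3 and C57 smoke LPS 3 lie among LPS and saline arrays respectively.

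LPS against saline after room air measures the response of the lung to endotoxin in each strain. In C57 lungs the genes that rose most were Saa3 (6.59 ± 1.32 log2 units, 96.1-fold; mean 12.6, SD 0.234, against 6.04, SD 0.0560; n = 3 and 3), the chemokines Cxcl2 (6.15 ± 1.23), Cxcl10 (5.81 ± 1.01) and Cxcl9 (5.80 ± 0.97), and Acod1, which makes the macrophage metabolite itaconate (6.14 ± 1.15). Of 21 cytokine and chemokine genes 19 rose, among them Tnf by 3.45 ± 0.74 and Il6 by at least 3.25; adjusted over the list alone, all 21 did. Il6 read 3.87, 3.92 and 3.94 with saline, where the 5th percentile of these arrays was 3.50, 3.63 and 3.58, so its rise is a lower bound. Of 18 interferon-stimulated genes 18 rose, among them Irf7 (2.94 ± 0.78) and Ifit1 (2.62 ± 0.62). So did 14 of 15 interferon gamma-induced genes, 13 of 14 acute-phase genes (14 adjusted over the list alone) and 14 of 16 NF-kB feedback genes, with Tnfaip2 up by 2.63 ± 0.53. Monocyte markers rose in 7 of 12 cases, with Adgre1, the F4/80 macrophage antigen, up by 2.00 ± 0.39, and 5 of 10 endothelial activation genes rose (8 adjusted over the list alone). Of 14 neutrophil markers 3 rose (9 adjusted over the list alone), including the decoy receptor Il1r2 (3.72 ± 0.83). S100a8 (2.07 ± 0.79, limma adjusted p = 0.074) and S100a9 (1.29 ± 0.64, adjusted p = 0.165) did not pass in this fit, whose spread includes the doubted pair. Unfolded protein and integrated stress response genes rose in 9 of 16 cases (11 adjusted over the list alone), with Hspa5 up by 0.93 ± 0.16.

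B cell genes fell in C57 after LPS, measured against saline arrays on which they were high. Relative to the mean of all arrays they averaged 0.99, 1.20 and 1.23 with saline and 0.53, 0.37 and 0.47 in room air alone. The list median was -1.35 against saline and -0.63 against room air alone, a reference chosen after seeing the data. Of 13 markers 9 fell (12 adjusted over the list alone), among them the B cell adaptor Bank1 (-2.08 ± 0.35), the antigen receptor component Cd79a (-1.84 ± 0.42) and the surface antigen Ms4a1 (CD20; -1.60 ± 0.40). Airway secretory genes fell in 4 of 12 cases, with the detoxifying enzyme Pon1 at -1.87 ± 0.36 and the secretoglobin Scgb3a2 at -1.29 ± 0.40. No ciliated marker passed (median -0.53). Heart muscle markers, whose source in a lung sample was not examined, had a median of -0.88 with 1 of 11 lower. In all, limma called 2316 of 14705 genes, 1684 higher and 632 lower, and 3367 without both doubted C57 arrays, 2239 higher and 1128 lower. Camera called 14 of 29 lists, fry 12, and camera with an estimated correlation 0: the adjusted p then was 0.29 for cytokines, for interferon gamma-induced, acute-phase, NF-kB, unfolded protein and B cell genes, 0.30 for interferon-stimulated, monocyte and endothelial activation genes, and 0.53 for neutrophil and ciliated markers. The correlation was estimated with both doubted arrays included, which can raise these values for LPS-response lists. The count of genes fell to 1121 without C57 air saline replicate 1, 1170 without replicate 2, 1344 without replicate 3 and 1235 without C57 air LPS replicate 3.

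In AKR lungs LPS raised genes of these families as well. Acod1 rose by 6.44 ± 1.15, Cxcl2 by 5.98 ± 1.23, Ccl3 by 5.90 ± 1.00 and Cxcl9 by 5.88 ± 0.97 (n = 3 and 3). BC018473 (probe set 10382846), a transcript known by a cDNA clone, went from 5.80 (SD 0.339) to 12.04 (SD 0.882), a rise of 6.24 ± 0.26. Cytokine and chemokine genes rose in 19 of 21 cases (21 adjusted over the list alone), with Tnf up by 4.05 ± 0.74 and Il6, again low with saline (3.65, 3.78 and 4.52), by at least 5.0. All 18 interferon-stimulated, all 15 interferon gamma-induced and all 16 NF-kB feedback genes rose, and 10 of 14 acute-phase genes did (11 adjusted over the list alone). Neutrophil markers rose in 12 of 14 cases, S100a8 by 4.28 ± 0.79 and S100a9 by 4.06 ± 0.64, and monocyte markers in 7 of 12 (8 adjusted over the list alone). Endothelial activation genes rose in 6 of 10 cases, and unfolded protein response genes in 5 of 16 (8 adjusted over the list alone; median 0.33). Lymphocyte genes rose too: 8 of 13 T cell markers (10 adjusted over the list alone) with Cd3g at 1.10 ± 0.23, 9 of 11 natural killer cell markers, and 3 of 6 regulatory T cell markers (4 adjusted over the list alone) with the lineage factor Foxp3 at 0.49 ± 0.12. Relative to the mean of all arrays, T cell markers averaged -0.50, -0.70 and -0.66 on the AKR air saline arrays, 0.31, -0.05 and -0.37 with LPS, and -0.07 and 0.01 on the AKR arrays with 3 weeks of room air alone, so their rise was measured against low saline arrays. The same holds for natural killer cell markers, at -1.27, -1.34 and -1.70 with saline, 0.12, 0.42 and -0.64 with LPS, and -0.79 and -0.43 in room air alone. It also holds for major histocompatibility complex genes, at -0.17, -0.15 and -0.39 with saline, 0.49, 0.75 and 0.11 with LPS, and 0.18 and 0.20 in room air alone. Of 13 B cell markers 1 rose, the IgE receptor Fcer2a (2.53 ± 0.23), as did 5 of 11 dendritic cell markers. Of the 8 genes of the major histocompatibility list 7 rose, such as B2m (0.70 ± 0.08).

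Genes that fell in AKR after LPS included the channel-interacting protein gene Kcnip4 (-2.04 ± 0.22), the carboxylesterase Ces1g (-1.73 ± 0.43), the aldehyde oxidase Aox3 (-1.66 ± 0.37) and Pon1 (-1.64 ± 0.36). The clock genes Per2 (-0.72 ± 0.17) and Per3 (-0.82 ± 0.26) fell, 3 of 11 circadian genes in all (5 adjusted over the list alone), together with 5 of 12 club cell and 2 of 12 ciliated cell markers. Heart muscle markers had a median of -0.80, with 1 of 11 lower. limma called 2479 genes, 1390 higher and 1089 lower, and 3333 without both doubted C57 arrays, which enter the estimate of the spread alone. Camera called 18 lists, fry 15, and camera with an estimated correlation 0: the adjusted p then was 0.11 for cytokine, interferon gamma-induced, NF-kB, neutrophil, natural killer cell and major histocompatibility genes, 0.17 for interferon-stimulated genes, 0.18 for T cell and acute-phase genes, 0.19 for monocyte and regulatory T cell markers, 0.21 for dendritic cell and endothelial activation genes, 0.23 for circadian genes, 0.44 for B cell and 0.54 for ciliated markers. Both doubted C57 arrays enter this estimate of the correlation too. The count of genes was 1368 without AKR air LPS replicate 2 and 1485 with the 6 arrays compared alone.

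The strains shared much of the LPS response. Across 14705 genes, which are not independent replicates, the log2 fold changes of AKR and C57 correlated at r = 0.794 (Spearman's rho 0.646); 742 genes rose in both strains where independent lists would share 159, 198 fell in both against 46.8, and 30 went opposite ways. The comparisons share no arrays.

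**Figure D2:**
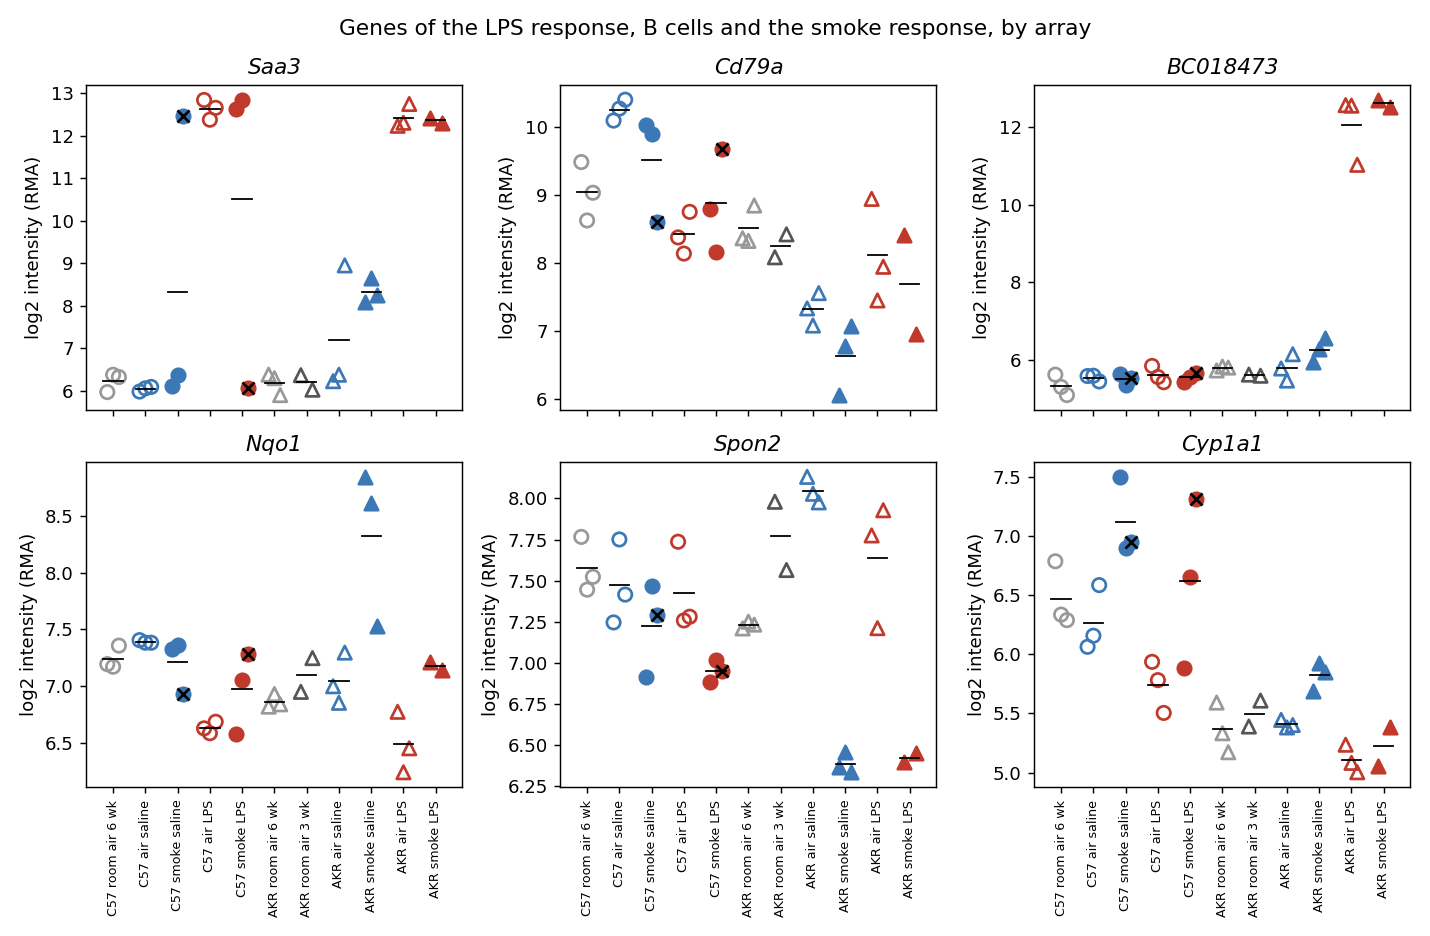
Log2 intensity (vertical axis) of Saa3, Cd79a, BC018473, Nqo1, Spon2 and Cyp1a1 on each array, by group (horizontal axis); bars are group means, circles C57, triangles AKR, filled symbols smoke, red LPS, blue saline, grey room air alone. Crosses mark the arrays labelled C57 smoke saline 3 and C57 smoke LPS 3, at 12.5 and 6.1 for Saa3; BC018473 is above 11 only on AKR arrays with LPS.

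Where the strains differed in the LPS response was tested as the interaction of strain and LPS after room air. BC018473 rose 6.17 ± 0.37 log2 units more in AKR, its change in C57 being 0.07 ± 0.26. Ifi202b, an interferon-inducible gene of little expression in C57BL/6, rose by 3.35 ± 0.35 more in AKR, and the interferon-induced GTPase Gbp2b by 2.61 ± 0.46. Complement C1q genes changed less or downward in AKR, C1qb by -1.48 ± 0.32 and C1qc by -1.17 ± 0.20 relative to C57. Of 13 B cell genes 9 were higher in the interaction (10 adjusted over the list alone; median 2.05, camera adjusted p = 3.9e-22 and 0.019 with an estimated correlation), among them Bank1 (2.83 ± 0.50) and Cd79a (2.63 ± 0.60). T cell markers passed in 2 of 13 cases (8 adjusted over the list alone, camera adjusted p = 0.14 with an estimated correlation). Natural killer cell markers did in 1 of 11 (5 over the list alone, 0.16 with an estimated correlation), with Klrd1 at 1.47 ± 0.34. Genes of the major histocompatibility list did in 2 of 8 (5 over the list alone, 0.061 with an estimated correlation), with Cd74 at 0.71 ± 0.17. No neutrophil marker passed (2 adjusted over the list alone, 7 without both doubted arrays; camera adjusted p = 9.3e-06, and 0.53 with an estimated correlation): S100a9 differed by 2.77 ± 0.90 (adjusted p = 0.17). Genes lower in AKR included the heat shock protein Hsph1 (-2.26 ± 0.43), the hydroxysteroid dehydrogenase Akr1c14 (-2.27 ± 0.54), Per2 (-1.12 ± 0.24) and 2 of 17 extracellular matrix genes (4 adjusted over the list alone), such as Col3a1 (-0.90 ± 0.20; list adjusted p = 0.16 with an estimated correlation).

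limma called 167 genes in this interaction, 118 higher and 49 lower in AKR, and 402 without both doubted arrays. The genes called depend on the reference. With the mice that had room air alone as the reference in both strains, a comparison chosen after seeing the data that also changes titled exposure time in C57 and has 2 AKR reference arrays, 109 genes were called, 14 of them among the 167. BC018473 (6.16), Ifi202b (3.35), Gbp2b (2.59), C1qb (-1.41) and C1qc (-0.98) passed there too, whereas the B cell median was 0.53 with 0 of 13 genes past the threshold, and Hsph1 changed sign (1.03). The count was 74 without AKR air LPS replicate 1, between 92 and 111 without any of C57 air saline replicates 1, 2 or 3 or C57 air LPS replicates 2 or 3, and 243 without C57 air LPS replicate 1. Of 20 settings, Klrd1 passed in 11, Cd74 in 9, Akr1c14 in 8, Col3a1 in 14, Cd79a in 15 and Per2 in 16.

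Smoke against room air in saline-treated mice shows what smoke did without endotoxin. In AKR lungs 5 genes passed (limma; 944 at an unadjusted p under 0.05). Nqo1 (probe set 10581538), a quinone reductase induced through NRF2 and the aryl hydrocarbon receptor, rose by 1.28 ± 0.22 (mean 8.33, SD 0.704, against 7.0, SD 0.226; n = 3 and 3), and the clock gene Per2 by 0.92 ± 0.17. Mthfd1l, of mitochondrial folate metabolism, rose by 0.82 ± 0.14 and Pmm1, of mannose metabolism, by 0.55 ± 0.10. Spon2 (probe set 10529264), an extracellular matrix protein, fell from 8.05 (SD 0.0790) to 6.38 (SD 0.0650), by 1.66 ± 0.17. Targets of the aryl hydrocarbon receptor shifted up as a list (median 0.41, camera adjusted p = 1.8e-05, and 0.0045 with an estimated correlation), with 1 of 5 past the threshold (2 adjusted over the list alone). Cyp1a1, its classical target, was at 0.41 ± 0.24 (limma adjusted p = 0.86). The receptor target past the threshold was Nqo1, which is also the 1 NRF2 target past it. Relative to the mean of all arrays, receptor targets averaged 0.80, 0.76 and 0.20 with smoke and -0.10, -0.25 and 0.13 with air. Smoke saline 3 thus lay near air saline 3. NRF2 targets shifted up (median 0.32; 1 of 18 passed, 6 adjusted over the list alone; adjusted p = 0.072 with an estimated correlation), with the cystine transporter Slc7a11 at 2.69 ± 0.82 (adjusted p = 0.32). By array, relative to the mean of all arrays, NRF2 targets averaged 0.54, 0.53 and -0.00426 with smoke and -0.20, -0.29 and 0.13 with air, so smoke saline 3 lay below air saline 3. The same arrays stood apart in endothelial genes, at -0.47, -0.54 and 0.03 with smoke and -0.15, 0.12 and -0.92 with air. Extracellular matrix genes shifted down (median -0.29, camera adjusted p = 6.9e-08, and 0.0060 with an estimated correlation): 0 of 17 passed, 7 adjusted over the list alone, with elastin (Eln) at -0.98 (adjusted p = 0.16) and Col3a1 at -0.56 (adjusted p = 0.15). Camera called 11 lists, 5 up and 6 down. B cell (median -0.36), dendritic cell (-0.19) and major histocompatibility complex genes (-0.34) were among those down, with every smoke array below every air array. Their adjusted p was 0.322, 0.274 and 0.166 with an estimated correlation. Circadian genes had a median of 0.46 (1 of 11 passed, 4 higher and 2 lower adjusted over the list alone; adjusted p = 0.32 with an estimated correlation).

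Without both doubted C57 arrays, which affect the AKR comparison through the spread alone, 49 genes passed, 31 higher and 18 lower, with Slc7a11 (adjusted p = 3.7e-04), the acute-phase protein Orm1 (2.52, adjusted p = 0.023), Per3 (1.12) and, downward, the clock activator Arntl (-1.05). The count was 26 without AKR air saline replicate 3 and 79 without AKR smoke saline replicate 3, 2 without AKR air saline replicate 1 or 2, and 1 without AKR smoke saline replicate 1 or 2. With the 6 arrays of these groups alone, 1 gene passed, Spon2 (adjusted p = 0.0034), and Nqo1 did not. Of the alternative settings, Spon2 passed in 14 of 14, Nqo1 in 8 of 13, Per2 in 8 of 14, and Mthfd1l and Pmm1 in 9 of 14.

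In C57 lungs no gene passed for smoke with saline (limma; 906 at an unadjusted p under 0.05; also 0 without both doubted arrays). Cyp1a1 was at 7.12 (SD 0.333) against 6.27 (SD 0.278), a difference of 0.85 ± 0.24 (adjusted p = 0.65), with all 3 smoke arrays above the air arrays; Per2 was at 0.61 ± 0.17 (adjusted p = 0.65) and Nqo1 at -0.18 ± 0.22 (adjusted p = 0.92). Camera called 13 lists, cytokines up (median 0.84) and B cell genes down (median -0.62) among them, and none with an estimated correlation, where their adjusted p was 0.715 and 0.309. The array labelled C57 smoke saline 3 drives the first, Saa3 being 2.27 ± 1.32 with it and 0.19 without the doubted pair. It carries part of the B cell shift too. B cell genes averaged 0.70, 0.86 and 0.04 on the 3 smoke arrays, relative to the mean of all arrays. Their median difference was -0.29 without the doubted pair. The strain by smoke interaction with saline called 0 genes (limma; 762 at an unadjusted p under 0.05), Nqo1 differing by 1.46 ± 0.32 (adjusted p = 0.40). In that interaction the extracellular matrix list was lower in AKR (median -0.39, camera adjusted p = 2.1e-07, and 0.016 with an estimated correlation). Of its 17 genes 6 passed adjusted over the list alone, and 0 over all genes. The array labelled C57 smoke saline 3, at 0.31 relative to the mean of all arrays, enlarges this difference. The other C57 smoke saline arrays were at -0.06 and -0.07. The NRF2 list was higher (median 0.47, camera adjusted p = 0.17 with an estimated correlation).

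Smoke against room air in LPS-treated mice asks whether smoke changes the lung after endotoxin. In AKR lungs Spon2 was again the gene that fell, by 1.22 ± 0.19 (adjusted p = 0.016; n = 2 and 3), and no other gene passed (limma; 2342 at an unadjusted p under 0.05). Macrophage genes shifted up (median 0.54; 0 of 16 passed, 6 adjusted over the list alone; camera adjusted p = 3.2e-04, and 0.34 with an estimated correlation), with the scavenger receptor Marco at 1.29 ± 0.36, the chitinase-like protein Chil3 at 1.66 ± 0.46 and Gpnmb, a marker of lipid-laden macrophages, at 1.06 ± 0.34. Ciliated cell markers shifted down (median -0.77; 11 of 12 adjusted over the list alone; camera adjusted p = 7.2e-10, and 0.34 with an estimated correlation), as did T cell (median -0.33) and natural killer cell markers (median -0.40), whose adjusted p with an estimated correlation was 0.341 and 0.515. Heart muscle markers also shifted down (median -0.75; 0.56 with an estimated correlation). Relative to the mean of all arrays, ciliated markers averaged 0.25, -0.59 and 0.21 with air and -0.60 and -0.96 with smoke, so air LPS 2 lay at the level of smoke LPS 1. Heart muscle markers averaged 0.86, -0.76 and 0.43 against 0.24 and -1.10. Natural killer cell markers averaged 0.12, 0.42 and -0.64 against -0.43 and -0.48, so air LPS 3 lay below both smoke arrays. T cell markers averaged 0.31, -0.05 and -0.37 against -0.31 and -0.50, so air LPS 3 lay below smoke LPS 1. Without both doubted C57 arrays 228 genes passed, 180 higher and 48 lower, among them Marco, Chil3, Gpnmb, tissue factor F3 (1.17), the alarmin Il33 (0.90) and, downward, complement C5 (Hc, -1.39). The count was 435 without AKR air LPS replicate 2, 0 without any other of the 5 arrays, and 0 with these 5 arrays alone; Spon2 passed in 8 of 13 settings.

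In C57 lungs no gene passed for smoke with LPS (limma; 217 at an unadjusted p under 0.05), nor without both doubted arrays; Cyp1a1 was at 0.88 ± 0.24 (adjusted p = 1.0), and 0.53 without the doubted array. Leaving out C57 smoke LPS replicate 1 gave 16 genes and replicate 2 gave 1, neither of them a doubted array. Camera called 14 lists and none with an estimated correlation; interferon gamma-induced genes had a median of -0.80 (adjusted p = 0.35 with an estimated correlation), in a group that holds the array at saline level. The strain by smoke interaction with LPS called 0 genes (limma; 1674 at an unadjusted p under 0.05), with Marco at 1.35 ± 0.48 (adjusted p = 0.43; named after its values were seen) and Chil3 at 1.72 ± 0.62 (adjusted p = 0.43).

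LPS against saline after smoke was the response to endotoxin in smoke-exposed mice. In AKR (n = 2 and 3) 4631 genes passed, 2491 higher and 2140 lower. Of these, 1177 rose and 759 fell after room air as well, and 0 went the other way. BC018473 rose by 6.34 ± 0.29, Acod1 by 6.26 ± 1.28, Clec4e, a receptor for mycobacterial glycolipid, by 5.95 ± 1.12 and Ccl3 by 5.93 ± 1.12. Cytokine genes rose in 20 of 21 cases (21 adjusted over the list alone), neutrophil markers in 12 of 14, monocyte markers in 9 of 12 and macrophage markers in 8 of 16, with the elastase Mmp12 up by 1.01 ± 0.22. The vessel-destabilising factor Angpt2 rose by 0.91 ± 0.25. Ciliated markers fell in 11 of 12 cases, club cell markers in 7 of 12, with Scgb3a2 at -2.52 ± 0.45, and circadian genes in 6 of 11 (8 adjusted over the list alone). Heart muscle markers moved the same way (median -0.95; 1 of 11 lower), averaging 0.93, 0.46 and -0.34 with saline and 0.24 and -1.10 with LPS. Ces1g (-3.19 ± 0.48), Aox3 (-2.55 ± 0.41) and Nqo1 (-1.15 ± 0.25) fell. Camera called 18 lists and none with an estimated correlation, where the adjusted p was 0.26 for cytokine, neutrophil, monocyte, macrophage, ciliated and circadian genes and 0.34 for club cell genes. The count was 2613 without AKR smoke LPS replicate 1 and 2365 without replicate 2.

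In C57 the same comparison called 0 genes (limma, with 1300 at an unadjusted p under 0.05), since 1 array of each group lies nearer to the other group in LPS-response genes. Saa3 differed by 2.21 ± 1.32 (limma adjusted p = 0.61). Without both doubted arrays 3048 genes passed, 1608 higher and 1440 lower, with Saa3 at 6.51, Cxcl2 at 6.23 and Tnf at 3.85, 20 of 21 cytokine genes and 18 of 18 interferon-stimulated genes up and 9 of 13 B cell genes down. Leaving out C57 smoke LPS replicate 3 alone gave 1881 genes, C57 smoke saline replicate 3 alone 18 and C57 smoke LPS replicate 2 alone 2. The interaction of smoke and LPS called 0 genes in C57 (1081 at an unadjusted p under 0.05; 0 without both doubted arrays) and 0 in AKR (992 at an unadjusted p under 0.05). In AKR 17 genes passed without both doubted C57 arrays, 14 higher and 3 lower, Marco (1.20, adjusted p = 0.048) among them.

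**Figure D3:**
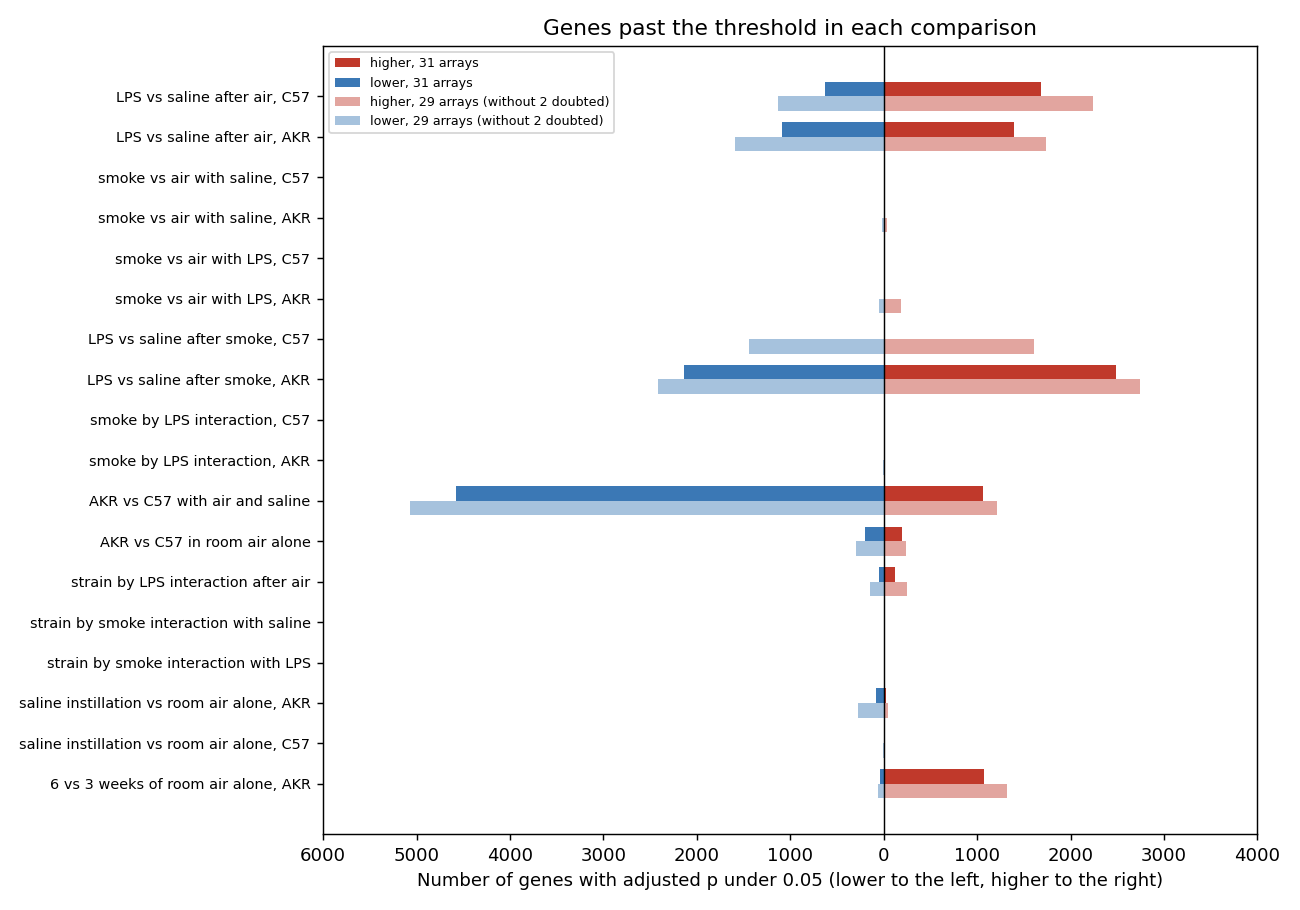
Number of genes past the threshold in each of 18 comparisons (horizontal axis; higher to the right in red, lower to the left in blue). Dark bars use all 31 arrays and pale bars leave out the arrays labelled C57 smoke saline 3 and C57 smoke LPS 3; LPS after smoke in C57 goes from 0 to 3048 genes.

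The strains were compared within 1 set of arrays in the room air groups titled 6 weeks (n = 3 and 3). Higher in AKR were the potassium channel Kcnma1 (12.95, SD 0.246, against 5.34, SD 0.155; 7.61 ± 0.54, and 3.72 as the mean of its probe sets), the class II antigen chain H2-Ea (at least 6.51, its C57 readings being background, since C57BL/6 mice do not express it), and 2 genes of known structural differences, Nnt (1.17 ± 0.12), deleted in part in C57BL/6J, and Glo1 (1.00 ± 0.12), duplicated in AKR. Lower in AKR were Trim12a (-3.94 ± 0.20) and Trim30d (-2.89 ± 0.50) of the antiviral Trim family, and Pttg1 (-2.47 ± 0.11). So were the natural killer cell receptors Klra8 (-1.99 ± 0.21) and Klrb1c (-0.64 ± 0.18, limma adjusted p = 0.049). Klrb1c passed in 3 of 13 alternative settings. Cyp1a1 was lower as well (5.37, SD 0.212, against 6.47, SD 0.275; -1.10 ± 0.24), while the receptor that drives it, Ahr, was at -0.34 ± 0.17 (adjusted p = 0.46). Complement C5 (Hc), whose protein AKR mice lack, was at -0.76 ± 0.38 (adjusted p = 0.46). limma called 396 genes, 192 higher and 204 lower (543 without both doubted arrays). Aryl hydrocarbon receptor targets were lower as a list (median -0.42; 1 of 5 passed; adjusted p = 0.17 with an estimated correlation), and natural killer cell markers too (median -0.44; 2 of 11 passed; adjusted p = 1.0 with an estimated correlation). The count fell to 228 to 254 without AKR air replicate 1 or 3 or C57 air replicate 2 or 3.

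With air and saline, a comparison that crosses the sets of arrays, 5640 genes passed, 1062 higher and 4578 lower in AKR, and the median of all genes was -0.16. Kcnma1 (7.67 ± 0.54), H2-Ea (at least 6.62), Nnt (1.22 ± 0.12) and Glo1 (0.94 ± 0.12) differed in the same direction as in room air. Trim12a was lower again, and by more than in room air (-4.96 ± 0.20). Of the genes called in both comparisons 120 were higher and 183 lower in each and 1 went opposite ways; independent lists would share 13.9 and 63.5. Natural killer cell (10 of 11; median -2.44), B cell (11 of 13; median -1.64) and T cell markers (11 of 13; median -1.08) were lower in AKR, as were 7 of 12 monocyte markers; the adjusted p with an estimated correlation was 0.55, 0.55, 0.68 and 0.94. Snord53, a small nucleolar RNA, was higher (4.20 ± 0.44) and the immunoglobulin gene Igha lower (-3.31 ± 0.30). Quantile normalization over all arrays gave 4966 genes, 2566 higher and 2400 lower, a balance that follows from giving all arrays 1 distribution; only differences within a set of arrays gave 1187, 432 higher and 755 lower.

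**Figure D4:**
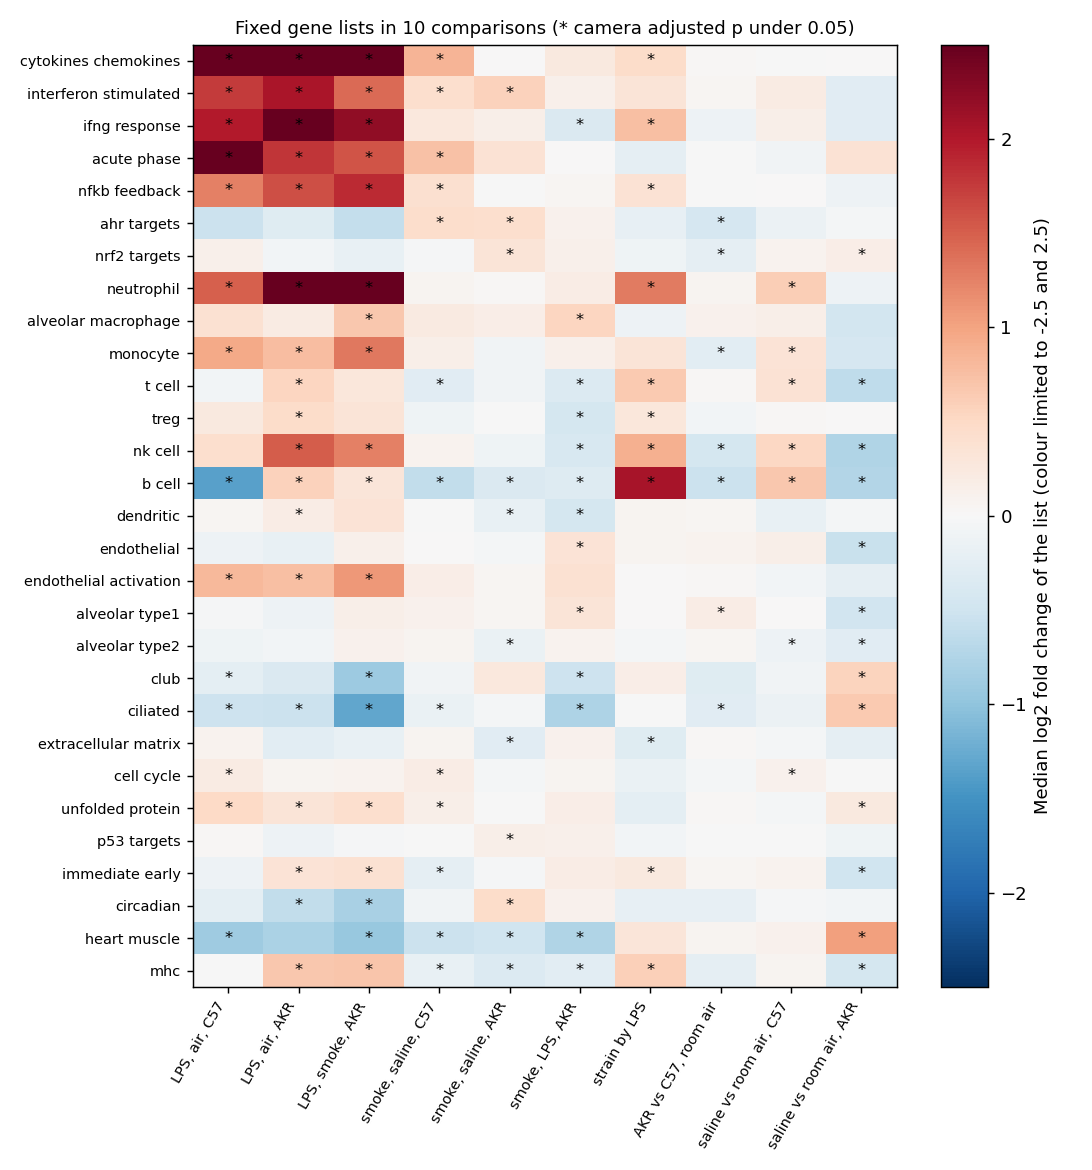
Median log2 fold change of 29 fixed gene lists (vertical axis) in 10 comparisons (horizontal axis), in colour from blue (lower) to red (higher); stars mark a camera adjusted p under 0.05 at the preset correlation. B cell genes have a median of -1.35 for LPS in C57, 0.58 for LPS in AKR and 2.05 for the difference.

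Saline instillation against room air alone is the background of the LPS comparisons. In AKR (n = 3 and 2) 101 genes passed, 19 higher and 82 lower (326 without both doubted arrays). The heat shock protein Hsph1 rose by 2.13 ± 0.34 and the small nucleolar RNA Rnu3a by 1.85 ± 0.32. Hsph1 read 9.80, 11.09 and 10.71 with saline, and 8.64 and 8.17 in room air alone at 3 weeks. On the AKR room air arrays titled 6 weeks, which lie in the other set of arrays, it read 8.74, 10.09 and 9.82. High readings thus occurred without instillation too. Serpinb10 (-2.44 ± 0.40), the incretin receptor Glp1r (-2.25 ± 0.50), the cytotoxic granzyme Gzma (-1.60 ± 0.36), the killer cell receptor Klrd1 (-1.22 ± 0.27) and Cd3g (-1.10 ± 0.26) fell. T cell markers passed in 2 of 13 cases (10 adjusted over the list alone) and natural killer cell markers in 2 of 11 (6 adjusted over the list alone), all downward, with an adjusted p of 0.48 for both with an estimated correlation. The same arrays read higher in heart muscle (median 1.03) and ciliated markers (median 0.66; 7 of 12 adjusted over the list alone) and lower in endothelial (median -0.56) and alveolar type 1 markers (median -0.47); the adjusted p with an estimated correlation was 0.51, 0.48, 0.54 and 0.51. The count was 8 without AKR air 3-week replicate 1, 1 without replicate 2, 17 without AKR air saline replicate 3, 167 without replicate 2 and 0 with the 5 arrays alone. Of 13 settings, Hsph1 and Serpinb10 passed in 11, Rnu3a in 9, Glp1r, Gzma and Klrd1 in 8, and Cd3g in 5.

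In C57, where instilled and control mice also differ in titled exposure time, 2 genes passed (limma; 907 at an unadjusted p under 0.05): Ripor2, a regulator of lymphocyte migration and RhoA, rose by 0.72 ± 0.11, and the lipid transporter Mfsd2a fell by 0.98 ± 0.17. The B cell (median 0.67), natural killer cell (0.52) and T cell lists (0.35) shifted up, opposite to AKR, with 4, 3 and 4 members adjusted over the list alone and an adjusted p of 0.31, 0.32 and 0.32 with an estimated correlation. Across genes the log2 fold changes of the strains correlated at r = -0.438 (rho -0.410); the difference between strains was not tested gene by gene. The count was 16 without both doubted arrays, 32 with the 6 arrays compared alone, and 0 without any of C57 air saline replicates 1, 2 and 3 or C57 room air replicate 2. Ripor2 passed in 10 of 14 settings and Mfsd2a in 7.

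The AKR room air arrays titled 6 weeks and 3 weeks (n = 3 and 2) lie in different sets of arrays, so time and set cannot be told apart. limma called 1115 genes, 1076 higher and 39 lower at 6 weeks, with a median of all genes of 0.13, and 335 genes, 154 higher and 181 lower, after quantile normalization. Klrb1c (1.97 ± 0.20), the class I gene H2-Q2 (1.59 ± 0.14) and the ribosomal protein gene Rpl34 (1.59 ± 0.12) were higher. Klrb1c read 4.27 and 4.23 on the 3-week arrays, where the 5th percentile was 3.23 and 3.25, so its difference may be a lower bound. Extracellular matrix genes shifted down (median -0.28, camera adjusted p = 1.4e-08, and 0.0064 with an estimated correlation), with Col3a1 at -0.67 ± 0.16 and the crosslinking enzyme Loxl1 at -0.61 ± 0.14, 2 of 17 past the threshold (3 adjusted over the list alone). Without any 1 of the 5 arrays the count lay between 146 and 670.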

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

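The permuted draws and the tests of the doubted arrays and of the strain difference with saline were chosen after the result was seen. For the B cell genes, room air alone as the reference was also chosen after the data were seen. The other B cell test leaves out the array with the highest Cd79a of its group, a choice that rests on the data.

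What is listed here is a difference between groups in an effect, tested as an interaction. For strain and LPS after room air, limma called 167 genes, and camera called 11 of 29 lists, and 1 with an estimated correlation, the B cell list. Genes that passed included, higher in AKR, BC018473 (6.17 log2 units), Ifi202b (3.35), Bank1 (2.83), Cd79a (2.63), Gbp2b (2.61) and Fcer2a (2.40), with Klrd1 at 1.47 and Cd74 at 0.71. Lower in AKR were, among others, Akr1c14 (-2.27), Hsph1 (-2.26), C1qb (-1.48), C1qc (-1.17), Per2 (-1.12) and Col3a1 (-0.90). Residuals of the 12 arrays were permuted in 100 draws, the real assignment included. Only 1 draw, the real one, reached 167 genes, and the highest other draw gave 0. The residuals came from a fit without the interaction and still hold it, which widens the spread in the other draws. Low counts are thereby favoured in those draws, so they do not exclude a random assignment as the source of the count. With room air alone as the reference, chosen after seeing the data, 109 genes were called, 14 of them among the 167, and Hsph1 was at 1.03, the reverse of its sign against saline (adjusted p = 0.224). That reference has no instillation in either strain, so how far the 167 genes rest on the saline arrays is open.

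Camera called lists in the other interactions, where limma called no gene: 14 for smoke and LPS in C57 (1081 genes at an unadjusted p under 0.05), 14 for smoke and LPS in AKR (992), 9 for strain and smoke with saline (762) and 13 for strain and smoke with LPS (1674). With an estimated correlation camera called 0, 0, 1 and 0 of them. In C57 both doubted arrays enter the smoke terms.

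The arrays labelled C57 smoke saline 3 and C57 smoke LPS 3 stand apart from their groups in LPS-response genes. On a scale from 0 at C57 air saline to 1 at C57 air LPS, over 666 genes called in AKR, they lie at 0.671 and -0.128. A failed instillation in 1 LPS mouse leaves the saline-labelled array at 0.671 unexplained, and a response to smoke alone is argued against by the other smoke saline arrays, the higher of which lies at -0.0233. An exchange of the labels would place the saline-labelled array among the LPS arrays, and it lies below the lowest other one (0.896) by a difference of -0.225, nearer to LPS than to saline. With 1 array on each side, an exchange cannot be told apart from 2 separate errors. The arrays keep their labels.

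Of the genes that differed between AKR and C57 with air and saline, 81.2% were lower in AKR. By differences within a set of arrays, in which an offset of a set cancels, the share was 63.6%. That leaves open how much of the excess comes from a difference between the 2 sets, such as a separate normalization, which no label states. A difference between the sets is not the cause of all the strain differences: 1098 of the 5640 genes, 19.5%, were called the same way by differences within a set. This comparison treats AKR room air at 3 and 6 weeks as equal. Of the other 4542 genes 52.99% were called the same way after quantile normalization over all arrays. That removes a difference in scale but no offset of single genes, so for these genes strain and set of arrays cannot be told apart. A real difference in lymphocyte content with saline stays open.

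B cell genes differed between the strains in their LPS response, with a list median of 2.05. Leaving out AKR air LPS replicate 1, which has the highest Cd79a of its group, gave 1.78, which argues against 1 array as the source, although 4 genes then passed. With room air alone as the reference the median was 0.533 and 0 of 13 genes passed, but that reference lacks instillation in both strains and changes titled exposure time in C57. Relative to the mean of all arrays, B cell genes averaged -0.69, -0.93 and -0.45 with saline in AKR, and -0.21 and -0.02 in AKR room air at 3 weeks. In C57 they averaged 0.99, 1.20 and 1.23 with saline, and 0.53, 0.37 and 0.47 in room air alone. A low lymphocyte content of the AKR saline arrays and a high one of the C57 saline arrays therefore cannot be told apart from a different response to LPS. Against room air alone the LPS medians were -0.63 in C57 and -0.09 in AKR, and against saline -1.35 and 0.58.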

How the results depend on the processing

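Results without both doubted arrays, by differences within a set of arrays, or with room air alone as the reference were chosen after seeing the data. Over the planned settings other than leaving out an array, 1581 of 1670 values for 212 named results kept their side of the threshold and direction, 43 became weaker, 46 stronger and 0 reversed; over leaving out each array, 1183 of 1378 did, with 180 weaker and 15 stronger. With room air alone as the reference, Hsph1 in the strain by LPS interaction reversed from -2.26 to 1.03.

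Weights per array changed most counts: LPS after air in C57 from 2316 to 7718, LPS after smoke from 0 to 4620 in C57 and from 4631 to 6981 in AKR, smoke with saline to 24 in C57 and 59 in AKR, smoke with LPS to 744 and 2668, and smoke by LPS to 186 and 108. They gave 2560 genes between strains in room air, 829 for strain by LPS, 2 and 710 for strain by smoke with saline and with LPS, 343 and 1273 for instillation in AKR and C57, and 4058 for weeks. The weights ran from 0.154 (AKR air saline 1) to 7.42 (C57 air LPS 3) with 2 or 3 arrays per group; the cause was not tested.

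With the groups compared alone, and so fewer arrays for the spread, the count was 1485 for LPS after air in AKR, 1 and 0 for smoke in AKR with saline and with LPS, 3 for smoke by LPS in AKR, and 0 and 32 for instillation in AKR and C57. The stricter filter gave 9 genes for smoke with saline in AKR, 1 for strain by smoke with saline and 697 for weeks, and no filter 2 for smoke with LPS in AKR, 1 for instillation in C57 and 2710 for weeks. Quantile normalization gave 12 and 2 for smoke in AKR with saline and with LPS, and 335 for weeks; limma-trend gave 12 for smoke with saline in AKR. The quantile normalization moved the median of all genes from -0.16 to 0.02 between strains with saline, and from 0.13 to -0.04 for weeks.

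Without both doubted arrays, which lowers the spread, the counts were 49 and 228 for smoke in AKR with saline and with LPS, 3048 for LPS after smoke in C57, 17 for smoke by LPS in AKR, 402 for strain by LPS, and 326 and 16 for instillation in AKR and C57. Differences within a set of arrays gave 1187 genes between strains with saline, against 5640. Room air alone as the reference gave 109 for strain by LPS, 14 of them among the 167. The replicate numbers do not pair the arrays (51 of 146 pairs with the same number had r above 0.1, median -0.0194); as a block they gave 1 gene for LPS after smoke in C57, 62 for instillation in AKR and 1 in C57.

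Of 218 list shifts called by camera, 5 held with an estimated correlation. That correlation was estimated with both doubted arrays under their labels, and no estimate without them was made. Their shared departures in LPS-response genes can raise it, so for those lists the lost calls do not measure robustness alone. Fry, counted over all lists and not among the 218 alone, called 68. The correlation of LPS responses, 0.794, was 0.773 with no filter, 0.814 with the stricter filter and from 0.738 to 0.806 without any 1 array. Leaving out 1 array gave from 1121 (without C57 air saline replicate 1) to 1860 (without C57 air LPS replicate 1) genes for LPS after air in C57, and from 1368 (without AKR air LPS replicate 2) to 2364 (without replicate 3) in AKR. For LPS after smoke it gave up to 1881 in C57 (without C57 smoke LPS replicate 3), and from 2365 (without AKR smoke LPS replicate 2) to 4229 (without AKR smoke saline replicate 3) in AKR. Smoke with LPS in AKR reached 435 without AKR air LPS replicate 2, strains in room air lay between 228 (without AKR air replicate 3) and 333 (without C57 air replicate 1), strain by LPS between 74 (without AKR air LPS replicate 1) and 243 (without C57 air LPS replicate 1), and weeks between 146 (without the 3-week replicate 1) and 670 (without the 6-week replicate 1). It gave up to 79 genes, against 5, for smoke with saline in AKR (without AKR smoke saline replicate 3), and, against 0, 8 for strain by smoke with saline (without that array), 1 for strain by smoke with LPS (without C57 smoke LPS replicate 1) and 3 for smoke by LPS in AKR (without AKR smoke saline replicate 3). A group left with 1 array takes its spread from the other groups.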

Other observations

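The tests by other splits of the arrays in this part were written down after the counts they test had been seen.

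With LPS after room air, of 20 endothelial genes 1 fell in C57 and 1 in AKR, alveolar type 2 genes went both ways (1 rose and 1 fell of 14 in C57, 2 and 2 in AKR), and no alveolar type 1 gene passed in either strain. Of 22 cell cycle genes 1 rose in each strain, and 1 of 9 p53 targets rose in AKR. Immediate early genes, which respond to handling as well as to signals, rose in 3 of 14 cases in C57 and 4 in AKR, and 1 fell with saline instillation in AKR. Thymocyte (1 gene tested) and adipocyte genes (4 tested) had 0 members past the threshold in any of the 18 comparisons by limma. Erythroid genes passed in 1 comparison, all 3 (Alas2, Fech and Slc4a1) being lower in AKR with air and saline (median -0.96), across the sets of arrays.

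Splits of the same arrays, 3 against 3, number 10 with the real one included, and are too few for a share under 0.05. The real split called 2316 genes for LPS after air in C57, and the highest other 15; for AKR these were 2479 and 1. Between strains they were 5640 and 0 with saline and 396 and 0 in room air. As many genes as the real split were reached by 1 of the 10 splits in each of these. For saline instillation in C57 the real count was 2, the highest other 2, and 2 of the 10 splits reached it. For smoke with saline in C57 the real count was 0 (906 genes at an unadjusted p under 0.05, limma), and the highest other 1; every one of the 10 splits reaches a count of 0 by construction, so this tells nothing about the grouping.

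In 3 of the comparisons another split called many more genes than the real one, which points to a structure of the samples other than the labels. For LPS after smoke in C57 the split that puts the array labelled smoke LPS 3 with smoke saline 1 and 2 called 3579 genes, against 0 for the real one. For smoke with LPS in C57 a split of air LPS 1 with smoke LPS 1 and 2 called 1712, against 0, the other side holding the array labelled smoke LPS 3. For smoke with saline in AKR a split of air saline 1 and 2 with smoke saline 3 called 557, against 5, and 2 of the 10 splits reached 5. In the first and second of these the real count is 0, which all 10 splits reach by construction.

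For interactions, 100 draws were made. Smoke by LPS in C57 and strain by smoke with saline had 0 genes each (1081 and 762 at an unadjusted p under 0.05, limma), and the highest other draws gave 827 and 1. All 100 draws reach a count of 0 by construction, so they say nothing about either interaction.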
